A study of Arabidopsis thaliana with 24 samples.

How the data were processed

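Transcript levels were measured on Affymetrix ATH1 arrays in whole Arabidopsis thaliana seedlings 7 days old, grown in light or in darkness. The genotypes were wild type (WT) and the lines csn5 (csn5a-2 csn5b), csn4-1 and csn3-1, called csn5-labelled, csn4 and csn3 here, which carry mutations in genes for subunits of the COP9 signalosome, a protein complex that removes the ubiquitin-like modifier NEDD8 from cullin ubiquitin ligases and that was found through mutants with light-grown features in darkness. The label of the csn5 line names mutations in both genes of that subunit. Each of the 8 groups held 3 arrays, 24 in all, and per the labels the 3 arrays of a group were independent biological replicates. About 80 mg of tissue was lysed per sample, total RNA was extracted on silica columns, and about 6 µg of RNA was turned into biotin-labelled cRNA, per the labels' protocols.

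The deposited values were signal intensities per probe set on a linear scale, 1 array per column, which the authors made with MAS5, per the submitters' processing notes. The MAS5 version, the scaling target and any filters were not given in the sources used here. In the values themselves the trimmed mean of every array lay close to 500. No scanner file was used here, so the step from probes to probe sets was that of the authors, and no detection calls were used. All 24 columns matched a sample by its identifier, and 0 columns of values per sample were left out. The direction of every difference was set by the labels.

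Each array was scaled to a 2% trimmed mean of 500, 50 was added, and log2 was taken, so that log2 differences of dim probe sets understate the ratio of signals. Of 22810 probe sets, 64 controls were left out. Of the 22746 others, the 18751 with a scaled signal of at least 100 in at least 3 arrays were tested. Median signals after scaling were 226, 225 and 181 in the csn3 dark arrays, 224, 226 and 247 in csn4 dark, 188, 192 and 184 in csn5-labelled dark, and 178, 188 and 187 in WT dark. In light they were 210, 200 and 215 in csn3, 229, 245 and 200 in csn4, 197, 194 and 223 in csn5-labelled arrays, and 183, 185 and 181 in WT. Pearson correlations between arrays of 1 group ran from 0.884 (csn4 light) to 0.988 (WT light), and the number of arrays per group limits the precision.

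A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and every comparison was a contrast of that fit. p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested in a contrast. A probe set was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size. All adjusted p-values of single genes are limma's. Each mutant and the mean of the 3 mutants were compared with WT in darkness and in light, light was compared with darkness in each genotype, the interaction of each mutant with light was tested, and mutants were compared with each other. Errors of log2 differences are standard errors of that fit, and errors of signals are SD over 3 arrays.

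Gene names came from the platform table supplied with the series, with symbols updated through a gene table of assembly TAIR10.1 that was used for names only. Of the probe sets other than controls, 13513 were listed with 1 gene, 503 with several and 8730 were unnamed here, and 13436 of the first kind matched the gene table. Of the tested probe sets, 10616 carried 1 gene name. No coordinates are given, since no genome build was named for the arrays' values. Genes without a symbol are named by locus.

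The genes named in the text followed a rule fixed before the data were examined. It took the mutated genes, then the 8 highest and 8 lowest of the csn mean in darkness and in light among probe sets called in all 3 mutants in 1 direction and separating all mutant arrays from all WT arrays, then the 8 highest and 8 lowest of WT light against dark, then the 4 highest and 4 lowest of each interaction and mutant pair, and up to 4 members of each gene list by adjusted p. A gene named outside that rule is said to have been chosen after its values were seen.

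The 24 gene lists, 505 genes in all, were also fixed beforehand. They covered COP9 signalosome subunits, DNA damage repair, G1 and S phase, G2 and M phase, inhibitors of cyclin-dependent kinases, core histones, photosynthesis, chlorophyll synthesis, regulators of photomorphogenesis, flavonoid and anthocyanin synthesis, auxin response, cell expansion, jasmonate, salicylate defence, ethylene, the 26S proteasome, cullin ligases, seed maturation, root markers, shoot apex and leaf markers, heat shock, oxidative and xenobiotic stress, carbon starvation and the circadian clock. Only 72 list genes had a probe set naming that gene alone, and 66 of them were tested. The salicylate defence and carbon starvation lists had 0 measured members, so they give no result. A further 7 lists had 1 member, whose value is given as that of a single gene. The remaining 15 lists were tested with camera at a preset correlation of 0.01, adjusted over these lists within a contrast, again with an estimated correlation, and with fry. The design fixed no minimum size. The test was first run with lists of at least 5 members, which were 4 lists, and was extended to all lists with at least 2 members after those values had been seen, because the design spoke of all lists. Of the 20 tests of those 4 lists, 9 had an adjusted p under 0.05 with an estimated correlation when adjusted over the 4 lists, and 1 when adjusted over all 15; with the preset correlation the count was 11 either way. A set of 26 further gene families with at least 8 members was chosen after the annotation and the values had been seen.

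Accession numbers fell into separate ranges, treated as a possible technical batch. The csn4 light and WT light arrays lay in one range and all others in another. Comparisons in darkness, csn4 with WT in light, and light with dark in csn3 and csn5-labelled arrays therefore lie within a range, whereas csn3 and csn5-labelled arrays with WT in light, and light with dark in WT and csn4, run across the ranges. A term for the range could not be fitted, since every group lies in 1 range. Two-sided exact permutation tests were used for array measures, with Benjamini-Hochberg adjustment over 18 tests.

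The alternatives were quantile normalization, an offset of 16, no filter, a filter at 200, a fit of the compared groups alone, eBayes without a trend, a term for growth condition by replicate number, each array left out in turn, and, for lists, an estimated correlation and fry. A covariate for the actin 3' to 5' ratio and a fit without the 4 arrays whose ratio was above 16 were added after the data had been seen. A pair of csn3 dark titles carried the number 1; the array that repeats it is called replicate 3 here and was left out where replicate numbers were used. The fit was tested on simulated data of 18751 probe sets in which the csn4 light group was changed. For csn4 against WT in light it recovered 99 of 100 simulated changes of log2 2 and 100 of 100 of log2 3, with 2 false calls, and for the csn4 interaction 85 of 100 and 100 of 100, with 4 false calls. In the mean of the mutants against WT in light, where a change in csn4 alone is diluted, it recovered 1 of 100 and 49 of 100 of the same changes, so changes in 1 mutant are mostly missed there. In camera, of 20 simulated lists with 20 members each, the 1 shifted list was found and 0 of the unchanged lists were called. Members were drawn independently of each other, so this run says nothing about false calls in the shorter and correlated lists tested here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.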

Results

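Transcript signals of 22746 probe sets were compared between seedlings of WT, csn3, csn4 and csn5-labelled lines grown in light or in darkness, 3 arrays per group. The percentage of probe sets with a scaled signal of at least 100 ran from 60.3 to 76.8 over the 24 arrays. Of the mutated genes, CSN5B had a probe set naming it alone, and CSN3, CSN4 and CSN5A were unnamed here.

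The CSN5B probe set was higher, not lower, in the arrays labelled csn5. Its signal was 1753 ± 165 (SD, n = 3) in csn5-labelled dark arrays and 140 in WT dark, and 805 ± 134 (SD, n = 3) in csn5-labelled light arrays and 118 in WT light. The log2 difference from WT was 3.26 ± 0.20 in darkness (limma adjusted p = 2.4e-13) and 2.34 ± 0.20 in light (limma adjusted p = 2.1e-10). In csn3 it was 0.50 in darkness and 0.64 in light, and in csn4 0.39 and 0.94, none of which passed. Where the probe set lies relative to the mutation was not known, so the value checks no label, and the arrays are called csn5-labelled throughout. In that line CSN5B was lower in light than in darkness (log2 difference -1.09), a call lost without csn5-labelled light replicate 3 (-0.95).

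The first comparison asked which transcripts differ between the mutants and WT in darkness. UGT78D2, a flavonoid glucosyltransferase, rose by log2 3.72 ± 0.18 in the mean of the mutants (n = 9 arrays against 3), and DFR, which reduces dihydroflavonols, by 2.81 ± 0.20. HYH, a bZIP factor related to HY5, rose by 2.79 ± 0.19. EXPA8, an expansin, fell by 3.77 ± 0.28, and WES1, which conjugates auxin to amino acids, by 2.42 ± 0.21.

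Of the genes named by the size of their change, AT2G25510 rose by log2 7.07 ± 0.19 in darkness (limma adjusted p = 4.4e-21), from a mean signal of 328 in WT. AT4G12490, of the lipid-transfer family, rose by 6.88 ± 0.19, AT5G62210 by 5.74 ± 0.18, AT4G12500 by 5.61 ± 0.27, AT5G55450 by 4.90 ± 0.20 and AT2G43620, a chitinase-like gene, by 4.54 ± 0.27. AT3G56290 and AT1G57770 rose by 4.57 and 4.55. JAL22, a jacalin-related lectin, fell by 5.60 ± 0.32 (limma adjusted p = 3.7e-14), AT4G11190, of the dirigent family, by 5.52, and SIS by 5.18 ± 0.28. AT2G16005, AT1G12080, AT3G53980, AT2G05540 and AT4G37220 fell by 5.40, 5.32, 5.17, 5.13 and 4.65.

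Of 4 flavonoid and anthocyanin genes measured in darkness, 3 rose, 0 fell and 1 did not pass, with the same counts when adjusted over the list alone. Besides UGT78D2 and DFR, the anthocyanin glucosyltransferase gene AT4G14090 rose by 2.101 ± 0.23, and AT5MAT, an anthocyanin malonyltransferase, had a log2 difference of 0.68. The list was higher in camera (adjusted p = 0.00623; adjusted p = 0.138 with an estimated correlation). Of 4 auxin response genes, 0 rose, 3 fell and 1 did not pass, 3 also when adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.138 with an estimated correlation). HAT2, an auxin-induced homeodomain factor, fell by 2.66 ± 0.33, and GH3.3, another auxin-conjugating enzyme, had a log2 difference of -0.86. The fall of IAA29 by 1.09 ± 0.23 was lost without WT dark replicate 2 (-0.94) and without csn3 dark replicate 3 (-0.99). It was also lost with the term for replicate number (-0.97) and without the 4 arrays of high actin ratio (-0.89). Of 4 cell expansion genes, 3 fell and 1 did not pass, and 3 fell when adjusted over the list alone (adjusted p = 0.0124; adjusted p = 0.138 with an estimated correlation). EXPA4 fell by 2.58 ± 0.30 and XTH19, a xyloglucan endotransglucosylase, by 2.32 ± 0.26. Of 5 root markers, 4 fell and 1 did not pass, and 4 fell when adjusted over the list alone (adjusted p = 0.00333; adjusted p = 0.0804 with an estimated correlation). PYK10, a root beta-glucosidase, fell by 1.84 ± 0.14, the peroxidase gene AT5G17820 by 2.69 ± 0.24, the root-hair expansin EXPA18 by 2.35 ± 0.35 and AT4G26010 by 2.03 ± 0.33.

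Counts of the lists that follow were the same when adjusted over the list alone. Of 9 photosynthesis genes in darkness, 4 rose, 1 fell and 4 did not pass (camera adjusted p = 0.458). RCA, the activase of Rubisco, rose by 2.91 ± 0.29, LHCB4.3, an antenna protein of photosystem II, by 2.08 ± 0.19 and PSAE-1, a subunit of photosystem I, by 1.39 ± 0.14, whereas LHCB4.2, another such antenna protein, fell by 2.47 ± 0.18. Of 7 chlorophyll synthesis genes, 1 rose and 6 did not pass (adjusted p = 0.793); PORB, a protochlorophyllide oxidoreductase, had a log2 difference of -0.83. Of the 2 regulators of photomorphogenesis, HYH rose and FHL, which acts in nuclear transport of phytochrome A, fell by 1.36 (adjusted p = 0.793). Of the 2 oxidative stress genes, AT2G21640 rose by 2.33 and GSTU25, a glutathione transferase, fell by 1.56 (adjusted p = 0.793). Of the 2 jasmonate genes, the defensin PDF1.2 rose by 1.47 and 1 did not pass (adjusted p = 0.689).

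Among cell cycle genes in darkness, 2 of 4 of G2 and M phase rose (adjusted p = 0.0710), the Aurora kinase gene AUR3 by 1.43 and BUBR1, of the spindle checkpoint, by 1.13, the latter call being lost without WT dark replicate 3 (0.97) and with quantile normalization (0.93). Of 4 core histone genes, HTB2 rose by 1.03 and HTB4 fell by 1.06 (adjusted p = 0.859). The HTB2 call was lost without WT dark replicate 2 (0.96) or replicate 3 (0.98) and without the 4 arrays of high actin ratio (0.93). The HTB4 call was lost without csn3 dark replicate 1 (-0.99), without WT dark replicate 3 (-0.94), without those 4 arrays (-0.96) and with quantile normalization (-0.996). In limma 0 of 2 DNA repair genes passed (1 at an unadjusted p under 0.05; camera adjusted p = 0.793), 0 of 2 G1 and S phase genes (0 unadjusted; 0.859), 0 of 6 proteasome genes (4 unadjusted; 0.859) and 0 of 2 shoot apex genes (1 unadjusted; 0.793). Of the lists with 1 measured gene, EIN3, a transcription factor of ethylene signalling, fell by 1.89 ± 0.20 and SIM, an inhibitor of cyclin-dependent kinases, by 1.55 ± 0.16. The values of CUL4, a cullin, of AT3G01570, an oleosin gene, of AT1G53540, a heat shock gene, and of the clock gene GI were 0.14, -0.29, -0.31 and -0.88 and did not pass.

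In all, 2539 probe sets were higher and 2190 lower in the mean of the dark mutants, 25.2% of the 18751 tested. Counts were 2674 and 2242 for csn3, 3266 and 2093 for csn4, and 2428 and 2440 for csn5-labelled arrays. The median of all probe sets was itself 0.18 higher in the mean of the mutants and 0.24 higher in csn4, and 0.07 and 0.05 after quantile normalization. That normalization turned the split from more higher to more lower probe sets in the mean of the mutants (2111 higher and 2368 lower), in csn3 (2239 and 2469) and in csn4 (2307 and 2608), and gave 2255 and 2368 in csn5-labelled arrays.

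**Figure D1:**
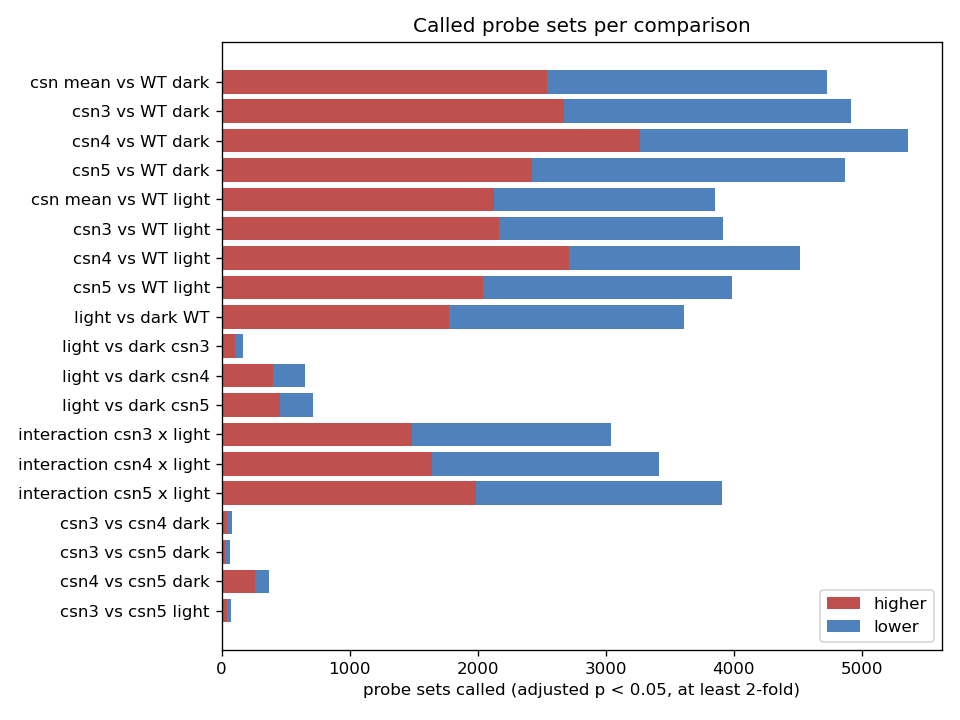
Horizontal bars give the number of probe sets called higher and lower in each comparison (axis from 0, adjusted p under 0.05 and log2 difference of at least 1). Light against dark gave 3609 calls in WT and 165 to 717 in the mutants.

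The mutants were compared with each other to ask whether their effects in darkness coincide. AT4G12490, JAL22, EXPA8 and UGT78D2 were among genes called in 1 direction in all 3 mutants. There were 1695 such probe sets higher and 1587 lower, 3282 in all, and 0 were called in opposite directions. Independent lists of these lengths would share 92.9. In 20 simulations of unchanged groups compared with the same simulated WT arrays, 0 were shared. The 3 comparisons together gave only 0.3 calls on average there. This 0 is therefore no measure of the overlap between lists of this length. Across genes, which are not independent replicates, the effects correlated at 0.93, 0.94 and 0.89 between pairs of mutants (0.50 simulated), with covariances of 1.01, 1.03 and 0.97 (0.04 simulated). Part of the excess of shared calls may come from the WT arrays the comparisons share, which at 3 arrays cannot be split; to the covariances these arrays add the simulated 0.04.

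Differences between mutants in darkness were few beside those from WT. AT2G47780 was higher in csn3 than in csn4 by log2 1.62 ± 0.21 (limma adjusted p = 0.00016). CSN5B was lower in csn3 than in csn5-labelled arrays by 2.76 ± 0.20, the peroxidase gene AT5G64120 by 1.95 ± 0.27 and AT4G22490, of the lipid-transfer family, by 1.94 ± 0.25, whereas AT1G30750 was higher by 1.63. Between csn4 and csn5-labelled arrays the defensin gene PDF2.5 was higher in csn4 by 2.69 ± 0.42, and AT4G12500, AT3G18280 and AT2G43620 were lower by 2.43 ± 0.34, 2.35 ± 0.27 and 2.32 ± 0.33. AT4G33560, AT5G66985 and AT3G18280 were higher in csn3 than in csn4 by 2.17, 1.87 and 1.72 and AT1G12080 lower by 1.88, calls lost in a fit of those groups alone.

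For csn3 against csn4 in darkness, 43 probe sets were higher and 41 lower, 84 in all, and 53 without csn4 dark replicate 3. With quantile normalization the split was 84 higher and 41 lower. For csn3 against csn5-labelled arrays the counts were 29 and 35 (16 and 33 with quantile normalization), 64 in all, and they fell to 25, 23, 33 and 25 without csn3 dark replicate 1, csn3 dark replicate 2, csn5-labelled dark replicate 2 and csn5-labelled dark replicate 3, or rose to 261 and 98 without csn3 dark replicate 3 and csn4 light replicate 2. For csn4 against csn5-labelled arrays they were 264 and 105 (80 and 162 with quantile normalization), 369 in all, and 96, 95, 237 and 143 without csn4 dark replicate 3 and csn5-labelled dark replicates 1, 2 and 3. Without csn4 light replicates 2 and 3 that total was 625 and 629.

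The same question was asked in light. GH3.3 fell by log2 3.54 ± 0.25 in the mean of the mutants (n = 9 arrays against 3), LHCB4.2 by 3.70 ± 0.18 and PORB by 2.32 ± 0.15. CHI, a chitinase, rose by 4.72 ± 0.27 (limma adjusted p = 5.1e-14) and DFR by 3.41 ± 0.20. Within the accession range that holds csn4 and WT light arrays, csn4 gave -4.07 ± 0.31 for GH3.3, -3.62 ± 0.22 for LHCB4.2, -2.39 ± 0.18 for PORB and 3.27 for DFR.

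AT3G28540 rose by 5.20 ± 0.38, AT4G12490 by 4.52 ± 0.19, and AT5G62210, AT1G17960, AT3G18250, AT3G44450 and AT5G60250 by 4.41, 3.95, 3.91, 3.84 and 3.81. AT3G16670 fell by 5.56 ± 0.32 and JAL22 by 4.75 ± 0.32 (limma adjusted p = 1.6e-12). AT5G62280, AT4G22490, AT2G33850, AT1G33811, AT2G05540 and AT3G45160 fell by 5.06, 4.78, 4.62, 4.42, 4.40 and 4.32.

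All 4 measured auxin response genes fell in light, 4 also when adjusted over the list alone: besides GH3.3, WES1 by 3.23 ± 0.21, HAT2 by 3.13 ± 0.33 and IAA29 by 2.51 ± 0.23 (camera adjusted p = 3.5e-05; adjusted p = 0.0486 with an estimated correlation). Of 9 photosynthesis genes, 0 rose, 6 fell and 3 did not pass, 6 also when adjusted over the list alone (adjusted p = 3.5e-05; adjusted p = 0.145 with an estimated correlation). The photosystem I gene PSAN fell by 2.60 ± 0.19, PRK, a kinase of the Calvin cycle, by 1.87 ± 0.18 and the photosystem II gene PSBY by 1.62 ± 0.17. Of 7 chlorophyll synthesis genes, 3 fell and 4 did not pass, 3 also when adjusted over the list alone (adjusted p = 5.4e-05; adjusted p = 0.0581 with an estimated correlation). CHLM, a methyltransferase of the magnesium branch, fell by 2.01 ± 0.14 and CHLI2, of magnesium chelatase, by 1.52 ± 0.21.

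Of 4 flavonoid and anthocyanin genes, 3 rose in light and 1 did not pass, 3 also when adjusted over the list alone (adjusted p = 0.000716; adjusted p = 0.0581 with an estimated correlation), AT4G14090 by 2.64 ± 0.23 and UGT78D2 by 2.25 ± 0.18. Of 4 cell expansion genes, EXPA8 fell by 3.06 ± 0.28 and EXPA4 by 2.52 ± 0.30 and 2 did not pass, 2 also falling when adjusted over the list alone (adjusted p = 0.00345; adjusted p = 0.0581 with an estimated correlation). Of 5 root markers, 4 fell and 1 did not pass, 4 also when adjusted over the list alone (adjusted p = 0.00477; adjusted p = 0.0581 with an estimated correlation), PYK10 by 1.56 ± 0.14 and AT4G26010 by 1.72 ± 0.33. The EXPA18 call (-1.11) was lost without csn3 light replicate 2 (-0.997). HYH rose by 1.84 ± 0.19, AT2G21640 by 3.03 ± 0.15 and GI by 1.31 ± 0.17, and EIN3 fell by 1.29 ± 0.20. FMA, of the stomatal lineage, fell by 1.03, a call lost without csn4 light replicate 2 (-0.996), csn4 light replicate 3 (-0.99), csn5-labelled light replicate 1 (-0.94) or WT light replicate 1 (-0.94). ATLIG4, a DNA ligase, rose by 1.22, and 0.73 with the actin ratio as a covariate did not pass. In limma 0 of 4 G2 and M phase genes passed (2 at an unadjusted p under 0.05), as did 0 of 4 histone genes (2 unadjusted), 0 of 6 proteasome genes (2 unadjusted), 0 of 2 G1 and S phase genes (1 unadjusted) and 0 of 2 jasmonate genes (0 unadjusted).

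In csn4 alone the same 6 lists passed camera in light. Auxin response fell in 4 of 4 genes (adjusted p = 1.4e-05; adjusted p = 0.0327 with an estimated correlation) and photosynthesis in 6 of 9 (adjusted p = 2.2e-05; adjusted p = 0.134 with an estimated correlation). Chlorophyll synthesis fell in 4 of 7 (adjusted p = 3.2e-05; adjusted p = 0.0614 with an estimated correlation), and flavonoid synthesis rose in 4 of 4 (adjusted p = 0.000978; adjusted p = 0.0650 with an estimated correlation). Cell expansion fell in 2 of 4 and root markers in 3 of 5, or 4 of 5 when adjusted over the list alone (both adjusted p = 0.00504; adjusted p = 0.0650 with an estimated correlation), the other counts being the same when adjusted over the list alone. The root peroxidase gene AT5G17820 fell by 1.31 in csn4, a call lost without csn4 light replicate 1 (-0.82), as were those of AT4G26010 (-1.26, then -1.02) and GSA1 (-1.09, then -0.89). The AT5MAT value of 1.03 in csn4 lost its call without csn4 light replicate 1 (0.96), csn4 light replicate 3 (0.98) or WT light replicate 3 (0.99), and with quantile normalization (0.48).

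In light 2130 probe sets were higher and 1727 lower in the mean of the mutants, 20.6% of those tested, with 2170 and 1746 for csn3, 2716 and 1804 for csn4 and 2042 and 1944 for csn5-labelled arrays. The median of all probe sets was 0.18 higher, or 0.21 in csn4, and 0.03 and 0.02 after quantile normalization. That normalization turned each of these splits to more lower than higher probe sets: 1652 higher and 1892 lower in the mean of the mutants, 1684 and 1860 in csn3, 1858 and 2126 in csn4, and 1648 and 2016 in csn5-labelled arrays. All 3 mutants shared 1385 higher and 1278 lower, 2663 in all, with 51.6 expected from independent lists, and 2 were called in opposite directions. The simulated value of 0 came again from 0.3 calls on average. Correlations across genes were 0.93, 0.93 and 0.88 with covariances of 0.81, 0.81 and 0.79, of which the shared WT arrays add the simulated 0.04, and part of the excess of shared calls may come from those arrays. The csn3 and csn5-labelled values against WT run across accession ranges, for which no term could be fitted, and csn4 against WT in light is the value within a range. Across the same ranges csn3 against csn4 in light gave 3 higher and 1 lower, and csn5-labelled arrays against csn4 119 and 242.

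Between csn3 and csn5-labelled arrays in light, GH3.3 was lower in csn3 by 1.88 ± 0.31 (limma adjusted p = 0.00237) and CSN5B by 1.70 ± 0.20. CHI and AT1G26410 were also called lower in csn3, and BAT1, MSRB6, SBT4.12 and AT5G17820 higher. Each of these calls was lost with some single array left out. There were 44 probe sets higher and 28 lower, 72 in all, and 33, 26, 20, 26 and 30 without csn3 light replicates 1, 2 and 3 and csn5-labelled light replicates 1 and 3.

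Light and dark were compared within each genotype to ask what light changes. In WT, RCA rose in light by log2 3.75 ± 0.36 (n = 3 arrays per group), PRK by 2.43 ± 0.22, CHLI2 by 2.47 ± 0.26 and PORB by 1.72 ± 0.18. CaS, a chloroplast calcium sensor, rose by 4.17 ± 0.18 (limma adjusted p = 1.3e-15). ICL, isocitrate lyase of the glyoxylate cycle, fell by 4.51 ± 0.27 (limma adjusted p = 3.9e-13).

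AT1G23130 rose by 5.77 ± 0.21 in WT, AT3G16670 by 5.14, AT2G33850 by 4.74, AT1G22690 by 4.42, AT3G48420 by 4.26, AT2G43620 by 4.16 and GSTU20, a glutathione transferase, by 4.11 ± 0.32. AT5G39520 fell by 5.75 ± 0.22, AT4G07820 by 5.05, AT4G37220 by 4.94, AT2G16005 by 4.85, AT4G11190 by 4.69, SIS by 4.31 ± 0.34 and AT2G47780 by 4.19. Of 9 photosynthesis genes, 8 rose and 1 did not pass, 8 also when adjusted over the list alone (camera adjusted p = 1.2e-08; adjusted p = 0.110 with an estimated correlation). Of 7 chlorophyll synthesis genes, 6 rose and 1 did not pass, 6 also when adjusted over the list alone (adjusted p = 6.1e-06; adjusted p = 0.0684 with an estimated correlation). GH3.3 rose by 3.01 ± 0.31, UGT78D2 by 1.501 ± 0.22 and SPCH, of the stomatal lineage, by 1.52 ± 0.38. SIM fell by 2.25 ± 0.20, GI by 1.83 ± 0.21 and AT3G01570 by 1.69 ± 0.25.

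In WT 1777 probe sets were higher in light and 1832 lower. The counts were 103 and 62 in csn3, 399 and 255 in csn4, and 458 and 259 in csn5-labelled arrays (343 and 294 with quantile normalization). The csn3 total of 165 was 414, 76 and 256 without csn3 dark replicates 1, 2 and 3, and 84 and 83 without csn3 light replicates 1 and 2, and the csn4 total of 654 was 1129 without csn4 light replicate 2. The WT and csn4 responses run across accession ranges, those of csn3 and csn5-labelled arrays lie within 1 range, and all 3 mutants had fewer calls than WT.

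**Figure D2:**
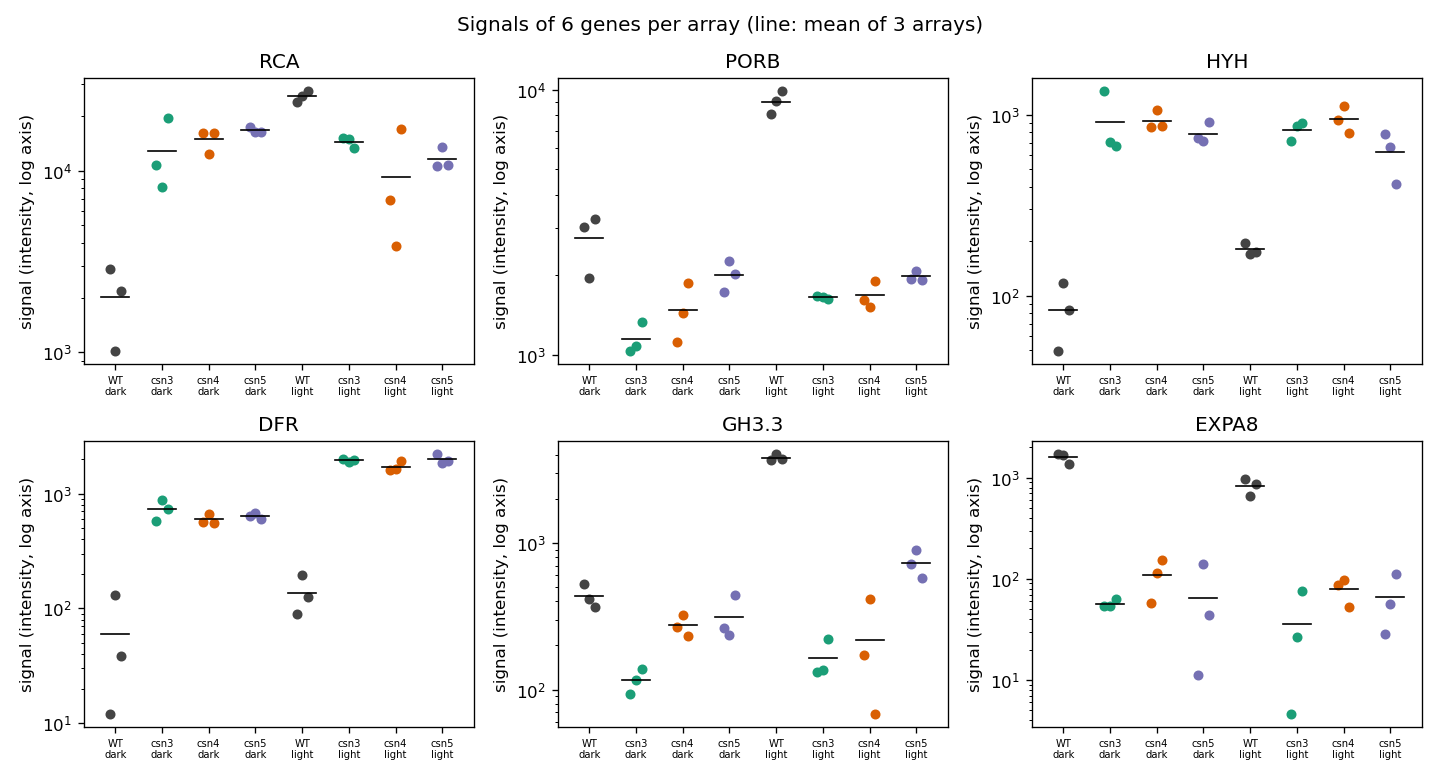
Signals (log axis) of RCA, PORB, HYH, DFR, GH3.3 and EXPA8 are plotted per array by group, with points for arrays and a line at the mean of 3. RCA rose by log2 3.75 from dark to light in WT, and EXPA8 was lower in the mutants in both conditions.

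Whether the mutant effect differs between light and dark was tested as an interaction. The light response of RCA was lower in csn4 than in WT by log2 4.69 ± 0.51 (limma adjusted p = 7.6e-08, n = 3 arrays per group), and that of AT3G16670 by 6.05 ± 0.55. PSAE-1, PRK and PSBY had interactions of -2.32 ± 0.24, -2.16 ± 0.31 and -2.12 ± 0.30, and CHLI2, GSA1 and HEMB1, enzymes of chlorophyll or tetrapyrrole synthesis, of -2.33 ± 0.37, -1.91 ± 0.27 and -1.62 ± 0.22. AT5G39520, which fell in WT light, had an interaction of 6.47 ± 0.32 (limma adjusted p = 6.2e-14), and CHI of 5.72 ± 0.46. In this contrast a difference between accession ranges cancels for csn4, and does not for the other mutants.

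All 9 photosynthesis genes had a negative interaction in csn4, 9 also when adjusted over the list alone (camera adjusted p = 3.7e-08; adjusted p = 0.129 with an estimated correlation). The same held for 6 of 7 chlorophyll synthesis genes, 6 also when adjusted over the list alone (adjusted p = 1.6e-06; adjusted p = 0.0477 with an estimated correlation). Of 4 auxin response genes 3 had a negative interaction, 3 also when adjusted over the list alone (adjusted p = 0.0131; adjusted p = 0.201 with an estimated correlation), among them GH3.3 at -3.50 ± 0.43; without csn4 dark replicate 2 the list had an adjusted p of 0.0518. SIM and GI had positive values, 1.62 ± 0.28 and 2.08 ± 0.29, and UGT78D2 a negative one, -1.47 ± 0.31. AT4G37220 and AT4G07820 had interactions of 5.51 and 4.60 in csn4, and AT1G23130 and AT1G66100, a thionin gene, of -4.72 and -4.61.

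All interactions subtract the same WT light response, from the same WT arrays, so a gene named for several mutants is not an independent result in each. In csn3 AT5G39520 had an interaction of 6.70 ± 0.32, CHI of 5.21, AT3G16670 of -5.29 ± 0.55, AT1G66100 of -4.85 and AT2G33850 of -4.84. In csn5-labelled arrays AT5G39520 was at 7.21, CHI at 5.70, AT4G33150, of lysine breakdown, at 4.88, AT3G16670 at -5.60, AT1G23130 at -5.32 and AT3G48420 at -5.14. Counts of positive and negative interactions were 1487 and 1555 for csn3, 1647 and 1766 for csn4, and 1990 and 1916 for csn5-labelled arrays. The last split turned, among others, with quantile normalization (1674 and 1886), an offset of 16 (1964 and 2015) and a filter at 200 (1819 and 1867). That of csn3 turned, among others, without the 4 arrays of high actin ratio (1750 and 1582).

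Because mutants of this complex were found by light-grown features in darkness, the genes that light changed in WT were followed in the dark-grown mutants. CaS was higher in each dark mutant than in WT dark, by log2 2.77 to 2.95. The 1777 probe sets that rose with light in WT had a median log2 difference of 1.00 in dark mutants (SD 0.10 over 9 arrays), where 889 were called higher and 53 lower. The 1832 that fell with light had a median of -1.18 (SD 0.15), with 1057 called lower and 43 higher. Unchanged groups, simulated around the WT dark means with simulated WT dark arrays shared by both sides, gave medians of 0.04 and -0.06. Their noise was independent between probe sets, so noise common to a whole measured array was left out. Sets sharing no array, taken from csn3 light against dark and measured as csn4 minus WT in darkness, gave 0.29 over 103 probe sets (32 higher, 16 lower) and -0.69 over 62 (10 higher, 26 lower). Across genes the WT light response correlated with the dark mutant effect at 0.57 (covariance 0.52, of which the WT dark arrays both sides share add a calculated 0.04). The csn3 light response and the csn4 effect in darkness, which share no array, correlated at -0.07. The csn3 response followed that of WT little, with a slope of 0.088 over the 3609 probe sets called in WT and 69 of them called in its direction. The sets from csn3 and the correlation of -0.07 therefore concern another response and do not test what the shared WT arrays add.

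**Figure D3:**
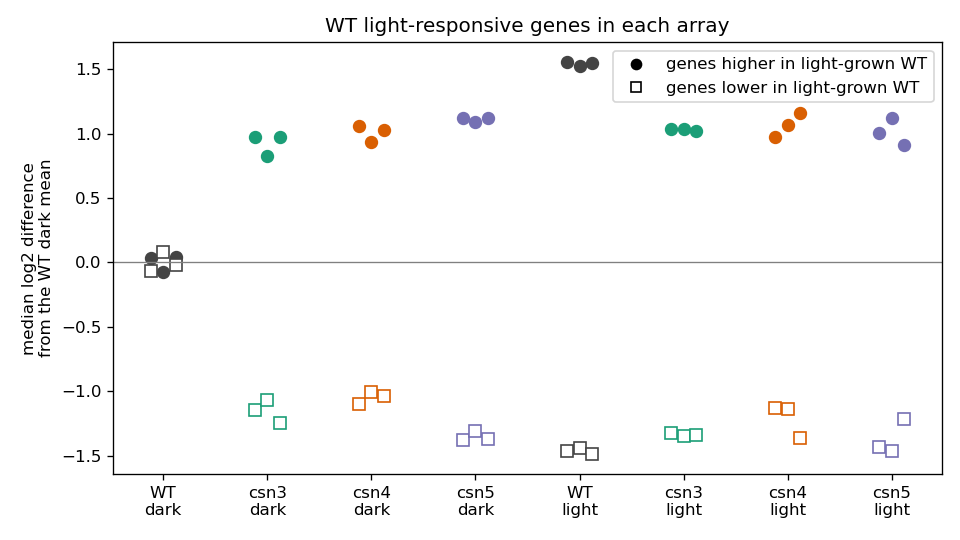
For every array the median log2 difference from the WT dark mean is plotted by group, for the 1777 probe sets that rose with light in WT (filled circles) and the 1832 that fell (open squares). Dark mutant arrays lie between 0.83 and 1.12 for the former, and between -1.38 and -1.005 for the latter.

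Over these 3609 probe sets, the slope of the light response of a mutant on that of WT was 0.088 for csn3, 0.069 for csn4 and -0.014 for csn5-labelled arrays. With each array left out it ran from 0.058 to 0.112 for csn3 and from 0.031 to 0.096 for csn4. For csn5-labelled arrays it ran from -0.041 to 0.017, so its sign was not stable. The median response of the probe sets that rose was 1.53 in WT, 0.10 in csn3, 0.04 in csn4 and -0.14 in csn5-labelled arrays, and of those that fell -1.45, -0.20, -0.21 and -0.05. Called in the direction of WT were 69, 155 and 120 of them, and in the opposite one 10, 51 and 118.

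Of the array measures compared between mutants and WT, the actin ratio and the 25S signal in light differed after adjustment. The log2 ratio of the actin 3' to 5' probe sets was 3.29 ± 0.93 in light mutants (SD, n = 9) and 1.48 ± 0.18 in WT light (SD, n = 3; two-sided exact permutation test, p = 0.00455, adjusted 0.0409 over 18 tests). The 25S ribosomal RNA signal was 26400 ± 7082 in light mutants and 3474 ± 2209 in WT light (SD, same exact p). These tests run across the ranges, since the csn3 and csn5-labelled light arrays lie in another range than WT light. In csn4 light, which shares the range of WT light, the log2 actin ratio was 3.92 ± 1.48 and the 25S signal 20060 ± 9408 (SD, n = 3). In light the log2 3' to 5' ratios of GAPDH (1.01 in mutants, 0.0375 in WT) and ubiquitin (1.28 and 0.558) did not pass (each exact p = 0.0455, adjusted 0.102). Nor did the 5S signal (2859 and 490, adjusted exact p = 0.184) or that of the cre spike (53740 and 24430, adjusted exact p = 0.164). In darkness the actin ratio was 3.58 ± 0.70 and 2.62 ± 1.65 (exact p = 0.177, adjusted 0.188), and 25S 10800 and 576 (exact p = 0.136). The median log2 signal of mitochondria-encoded probe sets was 9.52 ± 0.71 in dark mutants and 8.22 ± 0.48 in WT dark, and 8.76 ± 1.07 and 6.96 ± 0.07 in light (each exact p = 0.0182, adjusted 0.0655). For chloroplast-encoded probe sets it was 13.74 and 11.85 in darkness (exact p = 0.00909, adjusted 0.0546) and 13.36 and 12.69 in light (exact p = 0.196). The photosynthesis, chlorophyll and auxin genes that fell in light mutants did so in the arrays with these higher ratios. With the ratio as a covariate all 21 list calls made at the preset correlation held, as did 211 of 225 results of single genes. Those genes were named chiefly for the size of their change or as list members, and do not stand for all calls. Of all probe sets called in light, 2948 of 3857 in the mean of the mutants were still called with the covariate. In csn4 against WT in light 2659 of 4520 were. Among the named genes, the calls lost with it in light were those of EIN3 (-0.97), EXPA18 (-1.02), FMA (-0.98) and ATLIG4 (0.73) in the mean of the mutants. In csn4 they were those of CHLI2 (-0.96), GSA1 (-0.80), AT4G26010 (-0.84), ATLIG4 (0.94), AT5MAT (0.97) and AT1G53540 (1.005). Without the 4 arrays of high ratio the named genes whose calls were lost in light were FMA (-0.996) and, in csn4, AT1G53540 (0.88).

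**Figure D4:**
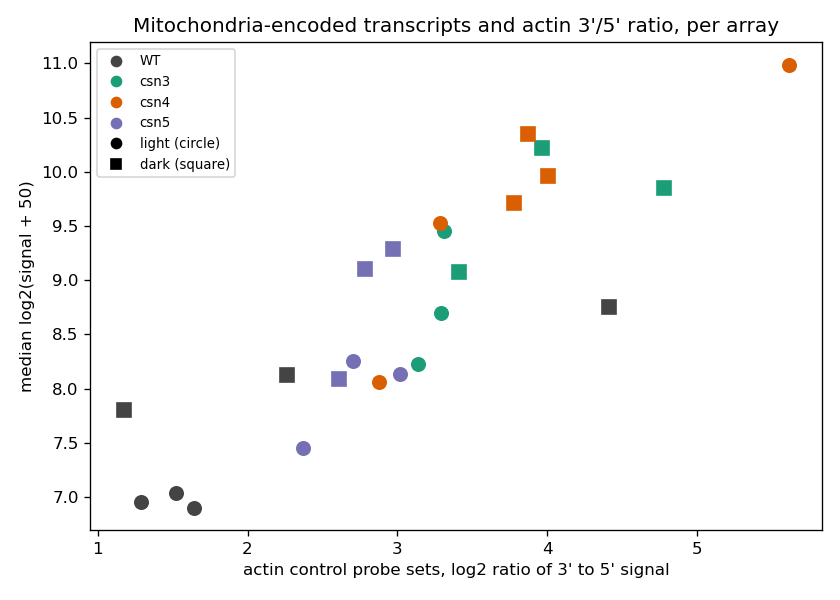
The median log2 signal of mitochondria-encoded probe sets is plotted against the log2 actin 3' to 5' ratio, 1 point per array, coloured by genotype (circles light, squares dark). WT light arrays sit lowest on the mitochondrial axis, at a mean of 6.96, with a mean log2 actin ratio of 1.48.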

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

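Chosen after the results were seen were the tests of the accession ranges and the regroupings with equal numbers of mutant arrays in dark and light. So were the fit without 4 arrays of high actin ratio and the actin covariate as an alternative. The other tests here were stated before. The set of mitochondria-encoded probe sets that 1 of them used was itself chosen after the annotation and the values had been seen. RCA, which rose with light by log2 3.75 in WT, had light against dark differences of 0.27, -0.94 and -0.52 in csn3, csn4 and csn5-labelled arrays, none of which passed. The interactions of genotype with light, 3042 probe sets in csn3, 3413 in csn4 and 3906 in csn5-labelled arrays, stood out because they test that difference itself.

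The slope of the mutant light response on that of WT was weighed first. A difference between the accession ranges would give csn4, which crosses the ranges as WT does, a slope of at least 0.5; its slope was 0.0693, and 0.0307 to 0.0964 with each array left out, which argues against the ranges as the cause. Uneven RNA quality would raise a mutant slope to 0.5 with the actin ratio as a covariate. The highest slope was 0.0672, and 0.0790 without the 4 arrays. The covariate moves a mutant's light response only by that mutant's own light against dark difference in the ratio. Mean log2 ratios in light and dark were 3.92 and 3.89 in csn4 and 2.70 and 2.79 in csn5-labelled arrays, so those slopes could hardly move. In csn3 they were 3.25 and 4.05. The test therefore does not decide on RNA quality, which stays open. The genotype stays open as a biological explanation and may account for the smaller response, a hypothesis found and tested on the same data.

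Chance was tested for the interactions by regrouping mutant and WT arrays within dark and within light. In the scheme stated beforehand, 11, 9 and 5 of 100 regroupings for csn3, csn4 and csn5-labelled arrays gave as many probe sets, the real one included, with highest other counts of 8611, 5760 and 7986, so that chance was not excluded by that test. All of those others, 10, 8 and 4, put unequal numbers of mutant arrays under the mutant label in dark and light, so they carry the genotype difference into the contrast, a structure of the samples. Among 82 regroupings with equal numbers, a scheme added after that outcome, 1 of 82 gave as many for each mutant and the highest other count was 0. Genotypes differ with or without an interaction, and these regroupings mix them within groups and raised the median residual SD from 0.307 to between 0.430 and 0.449 (log2), so few calls were set by their design and the scheme says nothing about chance.

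Pairs of mutants in darkness differed in 84 probe sets (csn3 and csn4), 64 (csn3 and csn5-labelled) and 369 (csn4 and csn5-labelled), and csn3 and csn5-labelled arrays in light in 72, each by a test of the difference. The larger count between csn4 and csn5-labelled arrays was weighed against RNA quality, for which the mean log2 actin ratio was 3.89 in csn4 dark and 2.79 in csn5-labelled dark. With the actin covariate that count was 0.782 times the higher of the other pairs (122 against 156), and without the 4 arrays 3.29 times (819 against 249). These point in opposite directions, so RNA quality cannot be told apart from a difference between the mutants. Leaving out single arrays moved the count of 369 from 95 (without csn5-labelled dark replicate 1), 96 (without csn4 dark replicate 3), 143 (without csn5-labelled dark replicate 3) and 237 (without csn5-labelled dark replicate 2) to 625 and 629 (without csn4 light replicates 2 and 3).

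The actin ratio and the 25S signal lie outside the main measurement and were higher in light mutants than in WT, at a mean log2 ratio of 3.29 and a mean signal of 26400. Mitochondria-encoded probe sets, also higher in the mutants, were weighed against this. With the actin covariate their median difference was 0.617 of the original in darkness and 0.401 in light, 0.239 to 0.908 with each array left out, around the stated limit of 0.5, so RNA quality as the cause cannot be told apart from a genotype difference. The lower of the medians within a range was 1.03 times that across ranges (0.867 to 1.196 with each array left out), which argues against the ranges. The genotype stays open, untested.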

How the results depend on the processing

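Chosen after the data were seen were the actin covariate and the fit without 4 arrays of high actin ratio; the other alternatives were stated before. No median, gene or list reversed; counts were scored by their totals alone. Of 28 counts and medians, 24 of 672 values with 1 array left out and 33 of 265 under other alternatives moved beyond the limits used (1.5 times for counts). Of 225 single-gene results, 7257 of 7415 values kept their direction and call and 158 lost the call. Of 21 list results 716 of 735 values kept both and 19 lost the call. Of these losses 18 fell under the estimated correlation, where only 3 of the 21 list results held. The direction with more calls turned in 34 of 456 splits of a count into higher and lower with 1 array left out and in 30 of 171 under other alternatives, 10 of them with quantile normalization. Between csn4 and csn5-labelled arrays in darkness 264 higher and 105 lower became 80 and 162 with that normalization and 57 and 65 with the actin covariate, and for csn4 light against dark 399 and 255 became 624 and 673 without the 4 arrays. Causes were not tested, except that a fit of the compared groups alone uses fewer arrays. The totals of all comparisons of the mutants with WT stayed within 1.5 times under all alternatives. So did those of WT light against dark, csn5-labelled light against dark, the interactions and the shared counts. The probe sets behind a total were not always the same: with the actin covariate 2659 of 4520 calls of csn4 against WT in light remained. Signals of dim probe sets lie near the offset, so small changes in them are not resolved.

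Between csn4 and csn5-labelled arrays in darkness the count of 369 was 242 with quantile normalization and 235 with a filter at 200. With the compared groups alone, counts were 107 for csn3 light against dark, 224 for csn4 light against dark, 10 for csn3 against csn4, 29 for csn3 against csn5-labelled and 589 for csn4 against csn5-labelled in darkness, and 193 for csn3 against csn5-labelled in light, which was 38 without the eBayes trend. With the replicate block, which also leaves out csn3 dark replicate 3, csn4 light against dark gave 394, csn3 against csn4 54 and csn3 against csn5-labelled 300, of which the last was 261 without that array alone; arrays of 1 number were not paired by the data, since 6 of 30 same-number correlations passed 0.1 (-0.34 to 0.24) and 10 of 23 arrays were closest to one of their number. With the actin covariate the dark pairs gave 156, 41 and 122. Without the 4 arrays csn3 and csn4 light against dark gave 536 and 1297, csn3 against csn4 249, csn4 against csn5-labelled 819, and csn3 against csn5-labelled in light 133. An offset of 16 moved the median of genes that rose with light in WT to 1.135 in dark mutants. The sets sharing no array, which came from the light response of csn3 and not from that of WT, gave 0.29 and -0.69.

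With single arrays left out, csn3 light against dark ran from 76 to 414, csn4 light against dark from 571 to 1129, csn3 against csn4 in darkness from 53 to 125, csn3 against csn5-labelled from 23 to 261, csn4 against csn5-labelled from 95 to 629, and csn3 against csn5-labelled in light from 20 to 101. Of the 4, 6, 6, 2 and 3 lists past camera for the mutants in darkness, in light, csn4 in light, WT light against dark and the csn4 interaction, 0, 1, 1, 0 and 1 passed with an estimated correlation. With fry 10, 10, 12, 8 and 7 passed. That test asks whether the genes of a list differ at all, and camera whether they differ more than other genes, so the fry counts do not offset the loss.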

Other observations

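The 26 gene families, and the genes named from them, were chosen after the annotation and the values had been seen, and all tests of them here are of that kind; the counts of splits were stated before. Of 8 ATG genes, of autophagy, 0 rose and 5 fell in darkness in the mean of the mutants (median log2 difference -1.37, -1.25 with quantile normalization; camera adjusted p = 0.000124 over 26 families; adjusted p = 0.0219 with an estimated correlation). ATG8E, an ubiquitin-like protein of the autophagosome, fell by 2.11 ± 0.14, ATG8H by 1.71 ± 0.16, ATG8F by 1.47 ± 0.13 and ATG8C by 1.44 ± 0.14, and ATG8B fell by 1.297 ± 0.16. In WT 4 of the 8 fell with light (median -1.06; adjusted p = 0.000103; adjusted p = 0.0152 with an estimated correlation), ATG8B by 3.36 ± 0.19. In light mutants 1 rose and 1 fell, ATG8B rising by 1.51 ± 0.16 and ATG8E falling by 1.94, and 3 had a positive interaction in csn4 (adjusted p = 0.00899; adjusted p = 0.115 with an estimated correlation).

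Of 9 expansin A genes, 5 fell in dark mutants (adjusted p = 0.0129; adjusted p = 0.329 with an estimated correlation) and 4 in light (adjusted p = 0.0116; adjusted p = 0.602 with an estimated correlation). Of 13 tetraspanin genes, 7 fell with light in WT (median -1.05; adjusted p = 0.0499; adjusted p = 0.614 with an estimated correlation), TET3 by 1.86 ± 0.18 and TET2 by 1.65 ± 0.22. Of 69 chloroplast-encoded genes, 59 rose in dark mutants (median 1.92, camera adjusted p = 8.7e-12, adjusted p = 0.604 with an estimated correlation). In light 31 rose (median 0.90, camera adjusted p = 7.7e-05, adjusted p = 0.715 with an estimated correlation). With the actin covariate 51 rose in darkness and 9 in light. These values are of the mean of the mutants. In light the median log2 signal of these genes, as a mean over 3 arrays, was 13.56 in csn3, 13.94 in csn4, 12.57 in csn5-labelled arrays and 12.69 in WT. By this measure csn5-labelled light arrays were not above WT. Of 15 mitochondria-encoded genes, 10 rose in darkness (median 1.43; adjusted p = 0.0323; adjusted p = 0.661 with an estimated correlation) and 12 in light (median 1.72; adjusted p = 0.00338; adjusted p = 0.655 with an estimated correlation), and with the actin covariate 7 and 5. ICL, which fell with light in WT, was higher in light mutants than in WT by 3.46, 2.76 and 3.36 in csn3, csn4 and csn5-labelled arrays.

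For comparisons of 3 arrays with 3, the real grouping was the 1 of 10 splits with as many calls in every case, which is too few splits for a share under 0.05. Against WT in darkness the highest other splits gave 75 for csn3 (4916 real), 1 for csn4 (5359) and 0 for csn5-labelled arrays (4868), and in light 0 for each (3916, 4520 and 3986). For light against dark they gave 0 in WT (3609), 1 in csn3 (165), 305 in csn4 (654) and 0 in csn5-labelled arrays (717). For pairs of mutants they gave 18 (84), 1 (64) and 1 (369) in darkness and 0 (72) in light. For the mean of the mutants, 100 of 220 splits of 9 and 3 arrays were drawn, and 1 of 100 gave as much in every case. This speaks against chance only under the assumption that all arrays of a growth condition are alike, the mutants among themselves included. The splits also mixed the mutants with each other, so a difference from WT alone was not tested. Mixed groups had a median residual SD of 0.319 to 0.427 in darkness and 0.311 to 0.413 in light (0.307 real), a rise that comes only from differences between the arrays mixed. The highest others were 1400 (4729 real) and 2 shared (3282) in darkness, 1084 (3857) and 0 shared (2663) in light, and sizes of 0.51 and 0.67 for the medians of genes that rose (1.00) and fell (1.18) with light in WT.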
